A study of Mus musculus with 12 samples.

How the data were processed

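Microglia, the resident macrophages of the brain, were purified on Percoll density gradients from C57BL6/J mice aged 3 to 4 months. The 12 libraries fall into 4 groups of 3: wild type (WT), wild type after lipopolysaccharide (WT-LPS), CPEB1 knockout (CPEB1-KO) and CPEB1 knockout after lipopolysaccharide (CPEB1-KO-LPS). Lipopolysaccharide (LPS), a component of bacterial outer membranes, was injected 24 h before the cells were collected. Each library came from 1 animal. Libraries were made from total RNA by poly(A) selection, so transcripts without a poly(A) tail, among them part of the non-coding RNA, are poorly covered. The injected dose, the sex of the animals and the read length are not given in the sources used here.

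The deposited files are 2 tables of 23845 genes by 12 libraries. The first holds expected counts per gene, which the authors did not normalise between libraries. Between 3.69% and 4.66% of its values are not whole numbers, and its columns sum to between 5.02 and 13.5 M (1e+06 counts). The second holds TPM (transcripts per 1e+06 transcripts) computed by the authors within each library, and each of its columns sums to 1e+06 within rounding. The submitters' processing notes name cutadapt, RSEM and the mm10 build of the mouse genome. Software versions, the aligner and any filters are not given in the sources used here. Of the gene names, 27 had been turned into dates and were restored from the transcript accessions in the same line. RefSeq held 23602 of the genes, and GENCODE M21 gave a position for 23485.

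Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as its argument, which left 15295 genes. Library sizes were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model with a mean for each of the 4 groups was fitted to all 12 libraries, with 8 residual degrees of freedom and a common biological coefficient of variation of 0.282. The 4 pairwise comparisons and the interaction, which is the LPS response in knockout minus that in wild type, were contrasts of this model. A second model with genotype and LPS as additive terms gave the average genotype difference over 6 libraries per genotype. Tests were two-sided, with the false discovery rate (FDR) of Benjamini and Hochberg at 0.05 over all genes of a comparison. Standard errors (SE) of log2 fold changes were the absolute change divided by the square root of the F statistic. Errors of TPM are standard deviations (SD) over 3 libraries.

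The gene lists, the rule for the genes named in the text and the first set of alternatives below were fixed before the data were examined. There were 28 lists with 451 entries. They cover the inflammatory response, microglial states, phagocytosis, the lysosome, nuclear and cytoplasmic polyadenylation, metabolism, the cell cycle, immediate-early genes, markers of other cell types and sex-linked genes. Of these entries, 5 were absent from the tables. Some members are held by more than 1 list: 6 of the disease-associated microglia list, 5 of the phagocytosis list, 4 of the lysosome list, 2 of the innate activation list and 1 of the homeostatic list. Lists were tested with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists of a comparison. The same test with the correlation estimated from the residuals stands beside it. Over the 6 comparisons, 62 of 168 tests passed 0.05 with the preset correlation and 2 passed with the estimated correlation. These 2 were cytokines and innate activation in CPEB1-KO-LPS against CPEB1-KO. Counts of members are given over all genes tested and, where they differ, adjusted over the list alone. Mean log2(TPM + 1) of a marker list was also compared between groups of 3 by a two-sided exact permutation test, whose smallest possible p is 0.1.

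The rule for the genes named in the text takes Cpeb1, up to 10 genes with the largest rise and 10 with the largest fall, up to 4 members of each list with the smallest unadjusted p, and 11 genes in every comparison (Tnf, Il1b, Il6, Ccl2, Cxcl10, P2ry12, Tmem119, Cx3cr1, Trem2, Cd68 and Mertk). The largest changes were taken among genes past FDR 0.05 with a mean of at least 5 TPM in a group, no overlap between groups and a name that is not that of a predicted gene. Where 5 or fewer genes passed, all are named. The other genes of the average genotype comparison, and Snap25, were named after their values were seen. A fold against a group with 0 counts is a lower bound computed against 3 counts over the group. With 1 to 3 counts the ratio of scaled counts is given with its exact 95% counting interval. Intervals and bounds cover counting error only, since reads were not marked by molecule. Differences that did not pass are not differences shown to be absent at depths of 5.02 to 13.5 M.

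The first set of alternatives comprised median-of-ratios size factors (RLE), DESeq2 1.42.0, no filter, a filter of at least 1 CPM (counts per 1e+06 counts) in 3 libraries, the replicate number as a block, and limma on log2(TPM + 1) or log2(TPM + 0.1). A threshold of 1.5-fold (glmTreat), fits of only the 2 groups compared and fits without each library in turn completed this set. Alternatives added after the data were seen were a neuron marker covariate, 3 libraries left out together, removal of the trend with gene length and thinning of all libraries to the smallest. Replicate numbers did not pair the libraries.

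The pipeline was tested on simulated data with the same libraries and genes. Of 50 genes planted at 2-fold, edgeR called 28%, DESeq2 40% and limma 28%. At 4-fold these shares were 86%, 100% and 88%. False calls made up 3.48% of calls by edgeR, 18.4% by DESeq2 and 5.13% by limma. In 2 comparisons with nothing planted, edgeR and limma made 0 calls, and DESeq2 made 3 and 4. A planted gene list had an adjusted p of 1.51e-20 with the preset correlation and 0.000212 with an estimated one, and 0 of 27 random lists passed. The simulated genes were drawn independently of each other. This simulation therefore cannot show how either setting of the correlation performs on lists of genes that vary together. The spread of each simulated gene was the one that edgeR estimated, and no library was set apart from its group. The shares of false calls may therefore favour edgeR and need not carry over to the real libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.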

Results

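Gene expression was measured in microglial preparations of wild-type mice and of mice labelled CPEB1 knockout, with and without LPS, in 3 libraries per group. CPEB1 is an RNA-binding protein that controls the length of poly(A) tails and the translation of mRNAs that carry its binding site. Total expected counts, in M (1e+06 counts), averaged 6.64 ± 2.48 M (SD, n = 3) in WT, 11.7 ± 1.18 M in WT-LPS, 11.3 ± 1.999 M in CPEB1-KO and 11.9 ± 2.29 M in CPEB1-KO-LPS. The shallowest libraries were WT replicate 2 (5.02 M) and WT replicate 3 (5.40 M). Between 16410 and 17661 genes had a count above 0 in a library.

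On the main axis of variation, which held 45.4% of the variance, the 6 LPS libraries lay apart from the 6 untreated libraries. The second axis held 19.7% of the variance and did not follow the groups. WT replicate 1, WT-LPS replicate 1, the 3 CPEB1-KO libraries and CPEB1-KO-LPS replicates 1 and 2 had positive values on it, and the other 5 libraries had negative values. Neuron markers were distributed in a similar way. Mean log2 CPM of the neuron marker list was 8.63 in WT replicate 1 against 7.43 and 7.42 in the other WT libraries, and 9.11 in WT-LPS replicate 1 against 7.94 and 7.99 in the other WT-LPS libraries. It was 8.64, 8.81 and 8.99 in CPEB1-KO. In CPEB1-KO-LPS it was 8.63, 8.79 and 8.22. Snap25, a protein of the neuronal synapse, ranged from 572 TPM in WT replicate 3 to 2439.8 TPM in WT-LPS replicate 1. Haemoglobin transcripts held 1.04% to 1.63% of counts in WT, 0.129% to 0.228% in WT-LPS and 0.576% to 0.847% in CPEB1-KO. In CPEB1-KO-LPS their share was 0.146%, 0.242% and, in replicate 3, 1.503%.

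**Figure D1:**
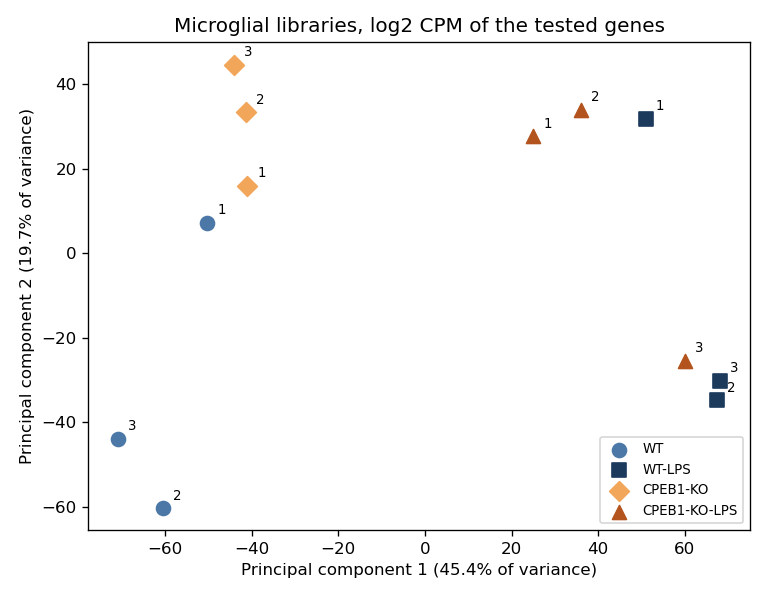
Principal components of log2 CPM, with component 1 on the horizontal and component 2 on the vertical axis. Each point is 1 of the 12 libraries, coloured by group and numbered by replicate. LPS and untreated libraries separate along component 1 (45.4% of the variance), whereas WT 1, WT-LPS 1 and CPEB1-KO-LPS 3 lie away from their own groups along component 2 (19.7%).

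The transcript of the targeted gene was present in the libraries labelled knockout, at a mean somewhat below that of wild type, and the difference did not pass the threshold. Cpeb1 (chromosome 7, 81347026 to 81455465 of mm10) had a mean of 26.2 ± 14.9 TPM (SD, n = 3) in WT and 21.8 ± 4.42 TPM in CPEB1-KO. With LPS these were 36.4 ± 10.98 TPM in WT-LPS and 33.1 ± 8.37 TPM in CPEB1-KO-LPS. Its counts ranged from 184 to 970 per library. Over both treatments the log2 fold change between knockout and wild type was -0.32 ± 0.23 (SE, 6 libraries per genotype, adjusted p = 0.543). It was -0.58 ± 0.31 without LPS (adjusted p = 0.334) and -0.07 ± 0.31 with LPS (adjusted p = 0.940). Gene-level values do not show which exons were read, so a deletion of part of the gene cannot be seen in them. The genotypes below are those of the labels.

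**Figure D2:**
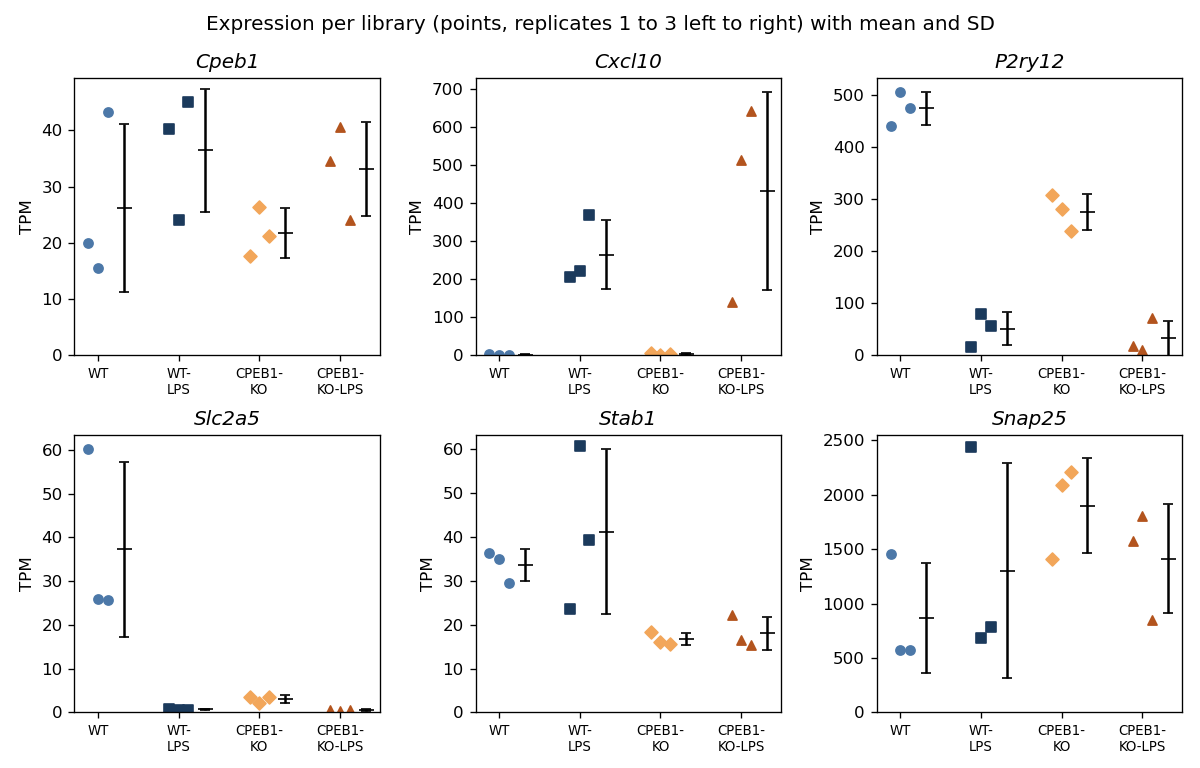
TPM of Cpeb1, Cxcl10, P2ry12, Slc2a5, Stab1 and Snap25 in each library, by group. Points are libraries, horizontal bars the mean of 3 libraries and error bars 1 SD. Cpeb1 overlaps between genotypes, P2ry12 is at 473 ± 32.4 TPM in WT and 50.8 ± 31.8 TPM in WT-LPS, and Slc2a5 is at 37.2 ± 19.96 TPM in WT and 3.08 ± 0.849 TPM in CPEB1-KO.

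WT-LPS against WT gave the response of wild-type microglial preparations 24 h after LPS. These preparations also held RNA of other cells, and the cells behind each change were not tested. Mean log2(TPM + 1) of the neuron list was 6.89 in WT and 7.75 in WT-LPS. That of the homeostatic microglia list was 7.47 and 5.61. Saa3, an acute-phase serum amyloid, went from 0.560 ± 0.970 TPM to 7883 ± 3201 TPM (SD, n = 3), a ratio of 8149 with a counting interval of 2788 to 39518. Lcn2, an iron-sequestering protein of innate defence, rose from 16.3 ± 7.81 TPM to 1232 ± 216 TPM (log2 fold change 5.85 ± 0.56, SE). Marco, a scavenger receptor for bacteria, had 0 counts in WT and 9449 in WT-LPS, which is at least 1782-fold higher. P2ry12, a purinergic receptor of resting microglia, fell from 473 ± 32.4 TPM to 50.8 ± 31.8 TPM (log2 fold change -3.56 ± 0.74). Each of the genes said to rise or fall in this comparison was outside the range of the other group in all 3 libraries, which chance alone gives for 10% of genes. No overlap was a condition for the largest changes, and list members were chosen by small p on the same values. For these genes it therefore adds no support.

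Among the 20 cytokines and chemokines tested, 18 rose, 0 fell, and 19 rose when adjusted over the list alone. Log2 fold changes were 6.39 ± 0.70 for Cxcl10, a chemokine for T cells, 6.71 ± 0.47 for the neutrophil chemokine Cxcl2, 3.92 ± 0.48 for the monocyte chemokine Ccl2 and 6.63 ± 0.94 for the cytokine Tnf. Il1b rose by 3.50 ± 0.75. Csf3, a growth factor for granulocytes, had 1 count in WT and 987 in WT-LPS, a ratio of 559 (counting interval 100.01 to 22082). Il6 was not past the threshold (log2 fold change 0.61 ± 0.55, adjusted p = 0.432). Of 22 innate activation and acute-phase genes 20 rose (21 adjusted over the list alone), with 8.08 ± 0.73 for the scavenger receptor Msr1 and 3.49 ± 0.31 for the copper carrier Cp. Of 20 genes of the NF-κB pathway and its feedback 15 rose (17 over the list alone). They include Tnfaip3 (5.86 ± 0.76), Nfkbiz (5.55 ± 0.69), Irak3 (4.14 ± 0.35) and Ier3 (3.32 ± 0.43). Of 25 interferon-stimulated genes 19 rose, both over all genes and over the list alone, such as Gbp2 (5.29 ± 0.62), Oasl1 (4.61 ± 0.75), Zbp1 (4.13 ± 0.66) and Ifitm3 (2.98 ± 0.40). With the preset correlation the adjusted p was 6.23e-21 for cytokines, 1.79e-33 for innate activation, 1.50e-13 for NF-κB and 3.20e-12 for interferon-stimulated genes. With an estimated correlation these adjusted p values were 0.228, 0.0684, 0.412 and 0.412, so none of the 4 calls held.

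Of 20 homeostatic microglia genes 11 fell and 0 rose (12 fell when adjusted over the list alone). The falls include the fructose transporter Slc2a5 (-6.04 ± 0.41), the receptor Gpr34 (-5.66 ± 0.70), Olfml3 (-3.83 ± 0.54), Tmem119 (-2.60 ± 0.59) and the fractalkine receptor Cx3cr1 (-1.98 ± 0.57). Crybb1, a crystallin gene among the 10 largest falls, changed by -5.66 ± 0.49. The list was called with the preset correlation (adjusted p = 1.70e-08) and not with an estimated one (adjusted p = 0.412). Disease-associated microglia genes split, with 3 of 19 higher and 5 lower (adjusted p = 0.737): Spp1 rose by 2.33 ± 0.34 and Ctsl by 1.40 ± 0.33, whereas Trem2 was at -2.71 ± 0.73 and Clec7a at -2.44 ± 0.56. Phagocytosis genes also split, with 6 of 28 higher and 4 lower (adjusted p = 0.213). The Fc receptor Fcgr4 rose by 4.60 ± 0.57 and Cd300lf by 6.52 ± 0.64, and Mertk, a receptor for apoptotic cells, was not past the threshold (0.37 ± 0.36, adjusted p = 0.460). Of 23 lysosomal genes 2 rose and 3 fell (adjusted p = 0.528), with Hexa at -2.47 ± 0.40 and Tfeb at -1.38 ± 0.24, while Cd68 did not pass (-0.80 ± 0.46, adjusted p = 0.210). The calls of Cx3cr1 and Trem2 were lost without WT replicate 2, without WT-LPS replicate 1 or without WT-LPS replicate 3, with adjusted p up to 0.0828 and 0.0544.

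Among genes that act on poly(A) tails in the cytoplasm, 8 of 23 rose and 0 fell, over all genes and over the list alone (adjusted p = 0.00167 with the preset correlation, 0.412 with an estimated correlation). They include the CPEB1 paralogs Cpeb2 (1.38 ± 0.23), Cpeb3 (1.36 ± 0.26) and Cpeb4 (1.06 ± 0.19) and the deadenylation factor Tob2 (0.73 ± 0.17). Cpeb1 itself was at 0.12 ± 0.31 (adjusted p = 0.791). Of 20 genes of nuclear cleavage and polyadenylation 4 rose and 3 fell (adjusted p = 0.164), with Pcf11 at 1.20 ± 0.22 and Rbbp6 at 1.05 ± 0.22. Glycolysis genes rose in 3 of 17 cases (adjusted p = 0.0214, 0.412 with an estimated correlation). These were the regulator Pfkfb3 (3.63 ± 0.49), the glucose transporter Slc2a1 (1.37 ± 0.21) and the transcription factor Hif1a (1.62 ± 0.27). Of 20 immediate-early genes 8 rose and 3 fell, or 11 and 3 over the list alone (adjusted p = 0.0464, 0.792 with an estimated correlation). Dusp2 rose by 3.88 ± 0.61 and Klf6 by 2.62 ± 0.50, whereas the heat shock genes Hspa1b and Hspa1a changed by -5.45 ± 0.53 and -2.84 ± 0.52. Antigen presentation had 4 genes higher and 1 lower of 16, or 5 and 2 over the list alone (adjusted p = 0.425), with Tap1 at 2.56 ± 0.54 and Nlrc5 at 2.74 ± 0.57. Oxidative phosphorylation (1 higher of 21, adjusted p = 0.793), cholesterol synthesis (3 higher and 1 lower of 17, adjusted p = 0.438), the cell cycle (1 higher of 19, adjusted p = 0.538) and sex-linked genes (1 higher of 4, adjusted p = 0.624) were not called. Over the list alone, oxidative phosphorylation and the cell cycle had 0 genes past the threshold and cholesterol synthesis 3 higher and 0 lower.

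Markers of other cell types also differed between WT-LPS and WT. All 7 choroid plexus and ependyma markers tested fell, among them Ttr (-2.08 ± 0.36), Kcnj13 (-3.85 ± 0.44) and Folr1 (-1.98 ± 0.29), with an adjusted p of 3.11e-07 (0.254 with an estimated correlation). Of 5 erythroid markers 4 fell, or 5 over the list alone (adjusted p = 0.00713, 0.472 with an estimated correlation), with Hbb-bs at -2.88 ± 0.72. The share of haemoglobin counts in every library is given above. Of 9 border macrophage markers 5 fell (adjusted p = 0.0118, 0.412 with an estimated correlation), with the mannose receptor Mrc1 at -2.36 ± 0.45. Of 6 B cell markers 3 fell, or 4 over the list alone (adjusted p = 0.0118, 0.487 with an estimated correlation), with Cd79a at -3.76 ± 0.73. Of 10 T and NK cell markers 4 fell, or 5 over the list alone (adjusted p = 0.0366, 0.661 with an estimated correlation). Of 8 monocyte markers 5 rose (adjusted p = 0.00235, 0.412 with an estimated correlation), with Ly6c2 at 2.93 ± 0.66 and Chil3 at 2.63 ± 0.48. Endothelial and mural markers split, with 6 of 16 higher and 4 lower (adjusted p = 0.514): Cldn5 rose by 1.85 ± 0.35 and Flt1 by 3.13 ± 0.62. Astrocyte markers (2 of 10 higher, adjusted p = 0.106), oligodendrocyte markers (3 of 12 lower, adjusted p = 0.0789), neuron markers (1 of 12 higher, adjusted p = 0.132) and neutrophil markers (0 of 11, adjusted p = 0.917) were not called, although Gfap, the intermediate filament of astrocytes, rose by 2.11 ± 0.38. Over the list alone, 1 astrocyte and 0 neuron markers passed.

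Of 15295 genes, 4185 passed FDR 0.05 in WT-LPS against WT, 1900 higher and 2285 lower, and 2812 of them changed at least 2-fold. With the authors' TPM the count was 4467, of which 75.7% were higher against 45.4% with counts. That setting, which differs in both the scaling and the tool (limma on log2 values), moved the median gene by 0.28 on the log2 scale. The count was 1720 for changes tested against 1.5-fold, 2592 in a fit of these 2 groups only and 2714 without WT-LPS replicate 3.

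CPEB1-KO-LPS against CPEB1-KO gave the LPS response in libraries labelled knockout. Saa3 went from 2 counts to 44547, a ratio of 21807 (counting interval 6036 to 180071), and Marco from 0 counts to 7349, at least 2398-fold higher. Cxcl10 rose by 6.90 ± 0.68 (log2, SE, n = 3 per group), Cxcl1 by 7.81 ± 0.60, Ccl2 by 5.16 ± 0.49, Tnf by 6.90 ± 0.94 and Il6 by 3.19 ± 0.56 (adjusted p = 0.00412). P2ry12 went from 275 ± 34.8 TPM to 33.2 ± 33.6 TPM (log2 fold change -2.89 ± 0.72, adjusted p = 0.0323).

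Of 20 cytokines 19 rose (20 adjusted over the list alone) and of 22 innate activation genes 21 rose, both over all genes and over the list alone. Their adjusted p was 1.52e-45 and 6.16e-57, and both calls held with an estimated correlation (adjusted p = 0.0316 and 0.00796). NF-κB genes rose in 15 of 20 cases (19 over the list alone, adjusted p = 1.96e-23, 0.187 with an estimated correlation), with Bcl3 at 5.03 ± 0.60, Nfkbia at 3.80 ± 0.52 and Irak3 at 3.51 ± 0.33. Interferon-stimulated genes rose in 14 of 25 cases (19 over the list alone, adjusted p = 2.82e-19, 0.187 with an estimated correlation), with Gbp2 at 4.47 ± 0.59, Oasl1 at 4.31 ± 0.68 and Mx2 at 2.48 ± 0.39. Before LPS, replicate 1 of CPEB1-KO had higher levels than the other CPEB1-KO libraries in several lists. Its mean log2(TPM + 1) was 3.75 against 2.67 and 2.49 for interferon-stimulated genes, 2.89 against 1.99 and 2.05 for cytokines, and 6.30 against 5.06 and 4.70 for antigen presentation. It was 2.89 against 1.22 and 0.95 for B cell markers and 2.41 against 1.34 and 1.15 for T and NK cell markers. Of 20 homeostatic genes 5 fell (10 over the list alone, adjusted p = 2.41e-09, 0.420 with an estimated correlation), with Gpr34 at -4.76 ± 0.68, Olfml3 at -3.28 ± 0.53 and Slc2a5 at -2.55 ± 0.40. Tmem119 (-1.52 ± 0.57, adjusted p = 0.144), Trem2 (-1.53 ± 0.70, adjusted p = 0.238) and Cx3cr1 (-0.36 ± 0.55, adjusted p = 0.766) were not past the threshold. Without CPEB1-KO-LPS replicate 3, Tmem119 and Trem2 passed. P2ry12 did not pass in the fits without WT-LPS replicate 3, any 1 of the CPEB1-KO libraries, CPEB1-KO-LPS replicate 1 or CPEB1-KO-LPS replicate 2 (adjusted p up to 0.113).

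Phagocytosis genes had 5 of 28 higher and 1 lower, or 7 and 2 over the list alone (adjusted p = 0.0122, 0.839 with an estimated correlation), with Msr1 at 7.16 ± 0.68, Fcgr4 at 3.68 ± 0.53 and Cd300lf at 5.55 ± 0.58. Of 7 choroid plexus and ependyma markers 5 fell (7 over the list alone, adjusted p = 1.09e-09, 0.0738 with an estimated correlation), with Kcnj13 at -2.90 ± 0.40 and Folr1 at -1.50 ± 0.28. Of 12 oligodendrocyte lineage markers 2 fell (adjusted p = 0.00104, 0.187 with an estimated correlation), among them Cspg4 of oligodendrocyte precursors (-1.76 ± 0.33). Gpr17, a receptor of the same precursors and one of the 10 largest falls, changed by -4.24 ± 0.42. Cell cycle genes had 1 of 19 higher (2 over the list alone, adjusted p = 0.0392, 0.790 with an estimated correlation). Hbb-bs was at 0.04 (adjusted p = 0.982), and without CPEB1-KO-LPS replicate 3, whose haemoglobin share is given above, it was at -1.73. The remaining 19 lists had an adjusted p of 0.0711 or more. Among them, 1 of 16 antigen presentation genes, 1 of 17 glycolysis genes and 1 of 10 astrocyte markers (Gfap, 2.04 ± 0.38) rose. Immediate-early genes had 4 of 20 higher and 2 lower, endothelial markers 1 of 16 higher and 3 lower, and monocyte markers 1 of 8 higher and 1 lower. In the other 13 of the 19, which are disease-associated microglia, lysosome, both polyadenylation lists, oxidative phosphorylation, cholesterol, neurons, border macrophages, neutrophils, T and NK cells, B cells, erythroid cells and sex-linked genes, 0 members passed over all genes. Over the list alone, antigen presentation had 4 genes higher, immediate-early genes 8 higher and 3 lower, monocyte markers 2 higher and 1 lower, and cytoplasmic polyadenylation and sex-linked genes 2 higher each.

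In CPEB1-KO-LPS against CPEB1-KO 952 genes passed FDR 0.05, 627 higher and 325 lower, 793 of them at least 2-fold, and 3136 genes had an unadjusted p under the threshold. DESeq2 called 1655, and 417 passed against 1.5-fold. The count was 607, 355 and 385 without CPEB1-KO replicate 1, 2 or 3, and 628 and 563 without CPEB1-KO-LPS replicate 1 or 2.

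**Figure D3:**
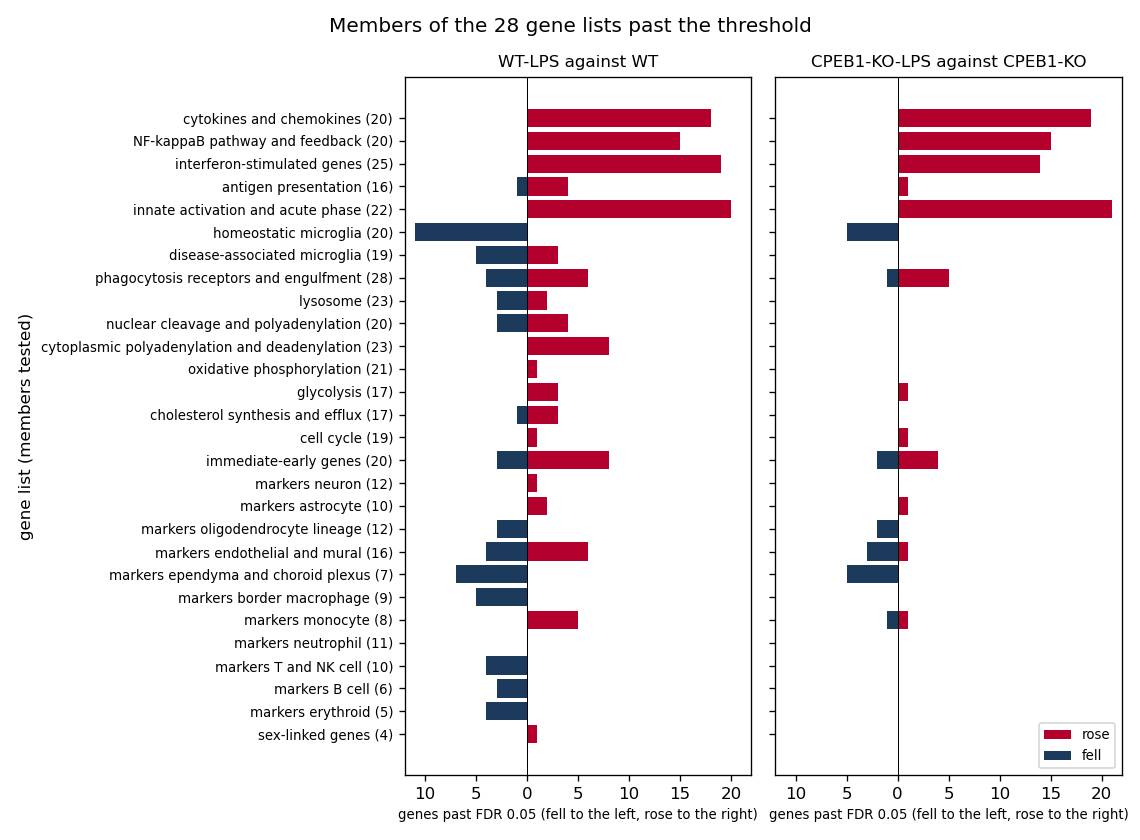
Number of members of each of the 28 gene lists past FDR 0.05 in WT-LPS against WT (left) and CPEB1-KO-LPS against CPEB1-KO (right). Bars to the right are genes that rose and bars to the left genes that fell, and the number of members tested stands in parentheses. Cytokines rose in 18 and 19 of 20 cases, and homeostatic microglia genes fell in 11 and 5 of 20.

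The interaction asked whether the LPS response differed between genotypes. Of 15295 genes 1 passed FDR 0.05, the pseudogene Gm5512 (chromosome 19, 12905320 to 12906841). Its levels were 27.5 ± 19.9 TPM in WT, 0.217 ± 0.116 TPM in WT-LPS, 1.40 ± 0.681 TPM in CPEB1-KO and 1.18 ± 0.567 TPM in CPEB1-KO-LPS (difference of responses 7.16 ± 0.94, log2, adjusted p = 0.0479). The responses of inflammatory genes were not shown to differ: the difference was 2.59 ± 0.78 for Il6 (adjusted p = 0.203), 0.27 ± 1.17 for Tnf (adjusted p = 0.931), 0.51 ± 0.90 for Cxcl10 (adjusted p = 0.813) and 0.68 ± 0.95 for P2ry12 (adjusted p = 0.760). Slc2a5 was at 3.49 ± 0.57 (adjusted p = 0.133), and Cpeb2, Cpeb3 and Cpeb4 were at -1.14 ± 0.32, -1.39 ± 0.36 and -0.99 ± 0.27 (adjusted p = 0.195 each). These differences also hold the genotype difference before LPS. In CPEB1-KO against WT, Cpeb2, Cpeb3 and Cpeb4 were at 0.54 ± 0.23, 0.96 ± 0.26 and 0.63 ± 0.19. Each was higher in every CPEB1-KO library than in every WT library, without passing (adjusted p = 0.235, 0.148 and 0.169). For the interaction, 2365 genes had an unadjusted p under 0.05, and DESeq2 called 293. Without WT replicate 1 edgeR called 441 genes, and without any 1 of the other libraries it called 0, except that Gm5512 also passed without CPEB1-KO-LPS replicate 2.

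The LPS responses of the 2 genotypes were compared gene by gene, with no library shared between them. Across 15295 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.68. In both comparisons 479 genes rose, against 77.9 for independent lists, and 270 fell, against 48.6. A further 2 genes passed in opposite directions. Of the 3434 genes past FDR 0.05 in WT-LPS against WT and not in CPEB1-KO-LPS against CPEB1-KO, 82.5% had the same sign in the latter. Over all tested genes this share was 67.7%. Of the 3434 genes, 928 had the same sign and an unadjusted p under 0.05 in the latter. The 4.40-fold difference in the number of calls is therefore not a count of genes with different responses. The slope of the knockout on the wild-type changes was 0.52 across genes. Noise in the wild-type changes lowers such a slope, so it alone does not show smaller responses.

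**Figure D4:**
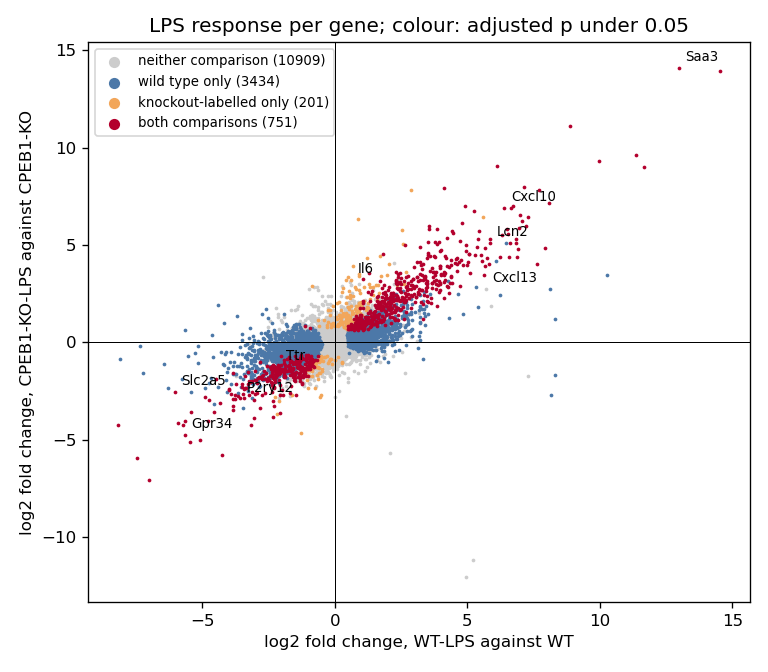
Fitted log2 fold change of each of 15295 genes in WT-LPS against WT (horizontal) and CPEB1-KO-LPS against CPEB1-KO (vertical), coloured by the comparisons in which it passed FDR 0.05. Saa3 and Cxcl10 lie far up in both and Gpr34 far down in both (r = 0.68 across genes), and values of genes with few counts are uncertain.

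CPEB1-KO against WT gave the genotype difference without LPS. All 5 genes past FDR 0.05 were lower in libraries labelled knockout. Gm13304 (chromosome 4, 42114817 to 42115917) was at 43.7 ± 20.1 TPM in WT and 0.933 ± 0.489 TPM in CPEB1-KO (log2 fold change -5.80 ± 0.52, SE, n = 3 per group, adjusted p = 0.000367). Slc2a5, the fructose transporter of microglia (chromosome 4, 150119283 to 150144169), was at 37.2 ± 19.96 TPM and 3.08 ± 0.849 TPM (-3.88 ± 0.35, adjusted p = 0.000367). The pseudogene Gm5512 was at -4.60 ± 0.57, the RNA-binding protein gene Taf15 at -1.63 ± 0.24 and Cuedc1 at -1.36 ± 0.19. In each of the 5 the 3 CPEB1-KO libraries lay below the 3 WT libraries.

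Homeostatic microglia genes were lower in CPEB1-KO as a list, with 19 of 20 members at a negative log2 fold change, 1 past FDR 0.05 (Slc2a5) and 2 adjusted over the list alone. The adjusted p was 6.08e-08 with the preset correlation and 0.968 with an estimated correlation. Single members had P2ry12 at -1.13 ± 0.68 (adjusted p = 0.376), Tmem119 at -1.12 ± 0.56 (adjusted p = 0.299) and Olfml3 at -1.84 ± 0.50 (adjusted p = 0.146). Phagocytosis genes (22 of 28 negative, 1 over the list alone, adjusted p = 0.000146), border macrophage markers (8 of 9 negative, 3 over the list alone, adjusted p = 0.0137), lysosomal genes (19 of 23 negative, adjusted p = 0.0235) and NF-κB genes (19 of 20 negative, adjusted p = 0.0447) were also called lower. Neuron markers were called higher, with 12 of 12 positive and 1 past the threshold over the list alone (adjusted p = 9.46e-06). With an estimated correlation the adjusted p was 0.968 for each of these lists. The other 22 lists were not called, and 0 of their members passed over all genes (over the list alone, 2 nuclear polyadenylation genes and 2 endothelial markers were lower). Instead of 6 lists, 14 were called without CPEB1-KO replicate 1, whose levels apart from its group are given above, and 3 without WT replicate 2. The neuron marker level was higher in all 3 CPEB1-KO libraries and in WT replicate 1 than in WT replicates 2 and 3, as given above. Cytokines were not called as a list (adjusted p = 0.373). Cxcl13, a chemokine for B cells, had 1 count in WT and 383 in CPEB1-KO (adjusted p = 0.169), nearly all from replicate 1 at 64.4 TPM.

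Besides the 5 calls, 2844 genes had an unadjusted p under 0.05, and DESeq2 called 500 genes, 118 higher and 382 lower. Without WT replicate 1 edgeR called 1292 genes, 523 higher and 769 lower, among them Stab1, Rac2, Gad1, Gad2, Mrc1 and Cbr2. It called 11 without CPEB1-KO-LPS replicate 3, 9 without WT-LPS replicate 1, 2 without CPEB1-KO replicate 2 or 3, and 3 without WT replicate 3, WT-LPS replicate 2, CPEB1-KO replicate 1, or CPEB1-KO-LPS replicate 1 or 2. Gm13304 and Slc2a5 passed in each of these fits, whereas Gm5512 was lost without CPEB1-KO replicate 2 or 3, Taf15 (adjusted p up to 0.421) without WT replicate 3, WT-LPS replicate 2 or 3, any 1 CPEB1-KO library, or CPEB1-KO-LPS replicate 1 or 2, and Cuedc1 (adjusted p up to 0.392) without any 1 of these libraries or WT replicate 2.

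CPEB1-KO-LPS against WT-LPS gave the genotype difference 24 h after LPS. Gm13304 again was lower, at 34.2 ± 16.3 TPM in WT-LPS and 0.350 ± 0.118 TPM in CPEB1-KO-LPS (log2 fold change -6.38 ± 0.57, adjusted p = 0.000582), and it was the only gene past FDR 0.05 with edgeR. Inflammatory genes were not past the threshold: Il6 was at 1.40 ± 0.49 (adjusted p = 0.422), Il1b at 1.55 ± 0.64 (adjusted p = 0.438), Tnf at -0.22 ± 0.70 (adjusted p = 0.916) and Cxcl10 at 0.86 ± 0.51 (adjusted p = 0.538). The chemokines Cxcl13 (4.69 ± 1.26) and Ccl7 (2.02 ± 0.46) were higher in every CPEB1-KO-LPS library than in every WT-LPS library, without passing over all genes (adjusted p = 0.361 each). Adjusted over the list alone, 2 of 20 cytokines passed.

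In the list tests of this comparison, lower values were called for monocyte markers (8 of 8 negative, adjusted p = 1.86e-06), immediate-early genes (19 of 20 negative, adjusted p = 2.00e-06), astrocyte markers (10 of 10 negative, adjusted p = 5.63e-06) and endothelial markers (13 of 16 negative, adjusted p = 4.37e-05). The same holds for phagocytosis (adjusted p = 0.000106), NF-κB (adjusted p = 0.000812), homeostatic microglia (adjusted p = 0.000921), cytoplasmic polyadenylation (adjusted p = 0.00206), and innate activation, the lysosome and cholesterol synthesis (adjusted p = 0.0332 each). Higher values were called for T and NK cell (adjusted p = 0.00911), erythroid (adjusted p = 0.0168) and border macrophage markers (adjusted p = 0.0332). With an estimated correlation none was called, the lowest adjusted p being 0.654. Adjusted over the list alone, 6 endothelial, 5 immediate-early, 3 monocyte and 3 phagocytosis genes were lower, and 4 erythroid genes and 1 border macrophage gene higher. Examples are Ly6c1 of endothelium (-1.67 ± 0.39), Ccr2 of monocytes (-2.06 ± 0.62), Egr1 (-1.55 ± 0.49) and the integrin Itgam (-2.04 ± 0.53). The other 14 lists were not called. CPEB1-KO-LPS replicate 3 had a neuron marker level of 8.22 and WT-LPS replicate 1 one of 9.11, each away from its group. Mean log2(TPM + 1) of the erythroid markers was 10.27 in CPEB1-KO-LPS replicate 3 against 7.22 and 7.95 in the other CPEB1-KO-LPS libraries and 7.33, 7.97 and 7.503 in WT-LPS, so these groups overlapped (exact permutation p = 0.7). Beside the 1 call, 1653 genes had an unadjusted p under 0.05 and DESeq2 called 90. The count was 11 without WT-LPS replicate 1, 6 without CPEB1-KO-LPS replicate 3 and 3 without CPEB1-KO replicate 1.

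Knockout against wild type over both treatments used all 12 libraries, with LPS as an additive term. Of 15295 genes 17 passed FDR 0.05, 3 higher and 14 lower in libraries labelled knockout. The lowest were Pnp2, a purine nucleoside phosphorylase gene (chromosome 14, 50955992 to 50964749), and Gm13304 (log2 fold change -6.03 ± 0.38, 6 libraries per genotype). Pnp2 had 52 counts in WT and 1 in CPEB1-KO, a ratio of 94.9 (counting interval 16.3 to 3819), and 37 counts in WT-LPS and 0 in CPEB1-KO-LPS, at least 13.01-fold lower. Rpph1, the RNA component of RNase P (chromosome 14, 50807449 to 50807767), was at 55.0 ± 13.9 TPM in WT and 2.10 ± 1.93 TPM in CPEB1-KO. These levels rest on 53 counts in WT and 3 in CPEB1-KO, a ratio of 32.2 (counting interval 10.4 to 161). With LPS there were 39 counts in WT-LPS and 1 in CPEB1-KO-LPS, a ratio of 41.1 (counting interval 6.96 to 1666). Most of the WT-LPS counts of Pnp2 and of Rpph1 came from replicate 1, as given below. Non-coding RNA without a poly(A) tail is poorly covered after poly(A) selection, as given above. The laminin receptor subunit Itga6 was at -1.61 ± 0.22, the immune regulator Lacc1 at -1.83 ± 0.27, the ribonuclease gene Ang at -2.70 ± 0.45, Ldb3 at -1.67 ± 0.24 and Mid1 at -1.95 ± 0.31. Stab1, a scavenger receptor that takes part in engulfment (chromosome 14, 31139013 to 31168641), was at -1.26 ± 0.22 (adjusted p = 0.0495), with 33.6 ± 3.69 TPM in WT, 16.7 ± 1.35 TPM in CPEB1-KO, 41.2 ± 18.7 TPM in WT-LPS and 18.0 ± 3.77 TPM in CPEB1-KO-LPS. The genes higher in knockout-labelled libraries were Serpina1b (3.21 ± 0.42), Anln (0.93 ± 0.15) and Gpx6, which had 3 counts in WT-LPS and 66 in CPEB1-KO-LPS, a ratio of 20.9 (counting interval 6.83 to 104). The others lower were Gm13157 (-2.93 ± 0.41), Gm3893 (-2.80 ± 0.45), Znf41-ps (-2.16 ± 0.34), 4933409K07Rik (-1.06 ± 0.18) and 9630013A20Rik, which had 24 counts in WT and 2 in CPEB1-KO, a ratio of 21.9 (counting interval 5.44 to 191). How reads were shared among similar gene copies is not given in the sources used here. Of the 17 genes 7 lie on chromosome 14 and 4 on chromosome 4.

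Over both treatments, the homeostatic microglia list was called lower, with 19 of 20 members at a negative log2 fold change, 0 past FDR 0.05 and 3 over the list alone (adjusted p = 6.97e-10). So was the phagocytosis list, with 27 of 28 members negative, 1 past FDR 0.05 (Stab1) and 2 over the list alone (adjusted p = 9.82e-09). Lower values were also called for immediate-early genes (adjusted p = 5.08e-07), NF-κB (adjusted p = 3.78e-05), the lysosome and monocytes (adjusted p = 0.000509 each), astrocytes (adjusted p = 0.00174) and endothelium (adjusted p = 0.00916). Neuron markers (12 of 12 positive, adjusted p = 0.000195) and oxidative phosphorylation (20 of 21 positive, adjusted p = 0.00664) were called higher. None held with an estimated correlation (lowest adjusted p 0.726), and the other 18 lists were not called. Without CPEB1-KO-LPS replicate 3, 16 lists were called instead of 10. Among inflammatory genes, C4b was at 1.34 ± 0.27 (adjusted p = 0.120), Il6 at 0.35 ± 0.52 (adjusted p = 0.772), and Cxcl13, with 1 count in WT, did not pass (adjusted p = 0.117). Adjusted over the list alone, 2 cytokines were higher and 1 lower, and 1 innate activation gene was higher.

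Without 1 library the count over both treatments went from 17 to 47 (CPEB1-KO-LPS replicate 3), 27 (WT-LPS replicate 1), 5 (CPEB1-KO-LPS replicate 2), 6 (CPEB1-KO replicate 3), 8 (WT-LPS replicate 3), 9 (CPEB1-KO replicate 1), 10 (CPEB1-KO replicate 2) or 11 (WT-LPS replicate 2), and it was 108 with DESeq2 and 6 against 1.5-fold. Gm13304, Pnp2, Rpph1, Itga6 and Serpina1b passed in all 12 of those fits, each of the other 12 genes failed in at least 1, and Stab1 passed only without WT-LPS replicate 1 (adjusted p up to 0.269 over all settings). Across genes, the genotype difference without LPS and that with LPS had a Pearson r of 0.025.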

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

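Of the tests in this part, the search for DNA of another strain away from Cpeb1, the neuron marker covariate and slope, the removal of the gene length trend, the thinning of libraries, the check of library labels and the splits of the libraries were chosen only after the result was seen.

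The LPS response differed between genotypes for 1 gene and 9 gene lists by the interaction test, and these are reported because a difference between groups passed its threshold. Gm5512 had a difference of 7.16 ± 0.94 (log2, SE, adjusted p = 0.0479). It was not called against 1.5-fold, with RLE size factors, with log2(TPM + 0.1), with log2(TPM + 1) over all genes above 0, with the neuron marker covariate, with the length trend removed, with thinned libraries, or without any 1 library other than WT replicate 1 and CPEB1-KO-LPS replicate 2 (adjusted p up to 0.325). The response was lower in knockout for cholesterol synthesis (15 of 17 members, adjusted p = 0.00965), neurons (12 of 12, adjusted p = 0.00725), astrocytes (10 of 10, adjusted p = 0.0124), monocytes (8 of 8, adjusted p = 0.0124), endothelium (10 of 16, adjusted p = 0.0337) and cytoplasmic polyadenylation (15 of 23, adjusted p = 0.0460). It was higher for border macrophages (9 of 9, adjusted p = 0.00228), erythroid cells (5 of 5, adjusted p = 0.00725) and T and NK cells (10 of 10, adjusted p = 0.00733). A difference of responses also holds the genotype difference before LPS. Mean log2(TPM + 1) of neuron markers was 6.89 in WT and 8.19 in CPEB1-KO, and 7.75 and 7.88 with LPS. For cholesterol synthesis it was 4.53 and 5.03, and 5.01 and 4.77 with LPS. Monocyte markers were at 2.89 and 2.90, and 4.82 and 3.50 with LPS. Astrocyte markers were at 6.22 and 6.46, and 7.12 and 6.28 with LPS. Erythroid markers were highest in CPEB1-KO-LPS replicate 3, at a mean log2(TPM + 1) of 10.27 against 7.22 and 7.95 in the other CPEB1-KO-LPS libraries, and without this library the LPS response of Hbb-bs in knockout went from 0.04 to -1.73. Adjusted over the list alone, 4 border macrophage and 4 erythroid genes and 1 endothelial gene were higher, and 5 endothelial and 3 cytoplasmic polyadenylation genes lower. With an estimated correlation none of the 9 was called (adjusted p 0.830 to 0.848), and without WT replicate 1 only 5 lists passed with the preset correlation. Across genes, the difference of responses had a Spearman correlation of -0.369 with gene length. The lists were not tested with that trend removed. Of the other 19 lists, which were not called, homeostatic microglia and nuclear polyadenylation had 1 gene higher each over the list alone. Of 100 splits of the libraries 7 gave as many genes as the real one (1 gene, highest other 824), so chance cannot be excluded for this count, and a split with 824 genes points to a structure of the samples.

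Between knockout and wild type over both treatments 17 genes were called, and 5 to 47 without 1 library, as named in the report. DNA kept from the embryonic stem cell strain around the targeted gene was argued against as a direct cause at the called genes with a position. None of these 16 lay within 20 Mb of Cpeb1 (edgeR, odds ratio 0). With 203 of 15151 tested genes there, few calls would fall there by chance, so this does not show that such DNA is absent. The gene with the lowest p there was Hddc3 (chromosome 7, 80343104 to 80350547), near Cpeb1 and short of the threshold (1.55 ± 0.28, adjusted p = 0.0623). RNA of neurons was argued against as the whole cause, since 13 of the 17 remained with the neuron marker covariate. DNA of another strain elsewhere in the genome may account for part of the 17, because chromosome 14, with 3.49% of tested genes, held 5 of 13 separate called loci, against a median of 3 for the fullest chromosome in 10000 draws (one-sided permutation p = 0.0265, a hypothesis found and tested on the same data). The genotype itself, reads shared among similar gene copies and a strain variant at each gene stay open as untested. Of 100 splits 3 gave as many genes, the real one included. This share argues against chance only if the libraries of a treatment are exchangeable. The highest other split gave 2577 genes, which points to a structure of the samples.

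In CPEB1-KO against WT, 5 genes were called by edgeR with all libraries and 1292 without WT replicate 1. A wrong label of WT replicate 1 was argued against by the genes called over both treatments without this library. At 11 of these 12 genes (91.7%) its level was nearer to the other untreated libraries labelled WT. The 1292 genes themselves were not used in this check. A difference of gene length trend was argued against as the whole cause, since 1106 of the 1292 calls remained with that trend removed. RNA of neurons stays open: 76.7% of these genes outside the neuron list moved in the direction that their slope on the neuron marker level predicts, against 67.1% of other genes, and with the covariate 7 genes were called. Genotype and the amount of neuronal material in each preparation cannot be told apart for these 1292 genes, because WT replicates 2 and 3 have the lowest neuron marker levels of the untreated libraries and are the only WT libraries left in that fit.

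LPS called 4.40 times as many genes in wild-type as in knockout-labelled libraries. Depth was argued against as the whole cause by the library totals, which averaged 6.64 M in WT and 11.3 M in CPEB1-KO. Lower depth lowers the power of a comparison, so it would give fewer calls in wild type. The ratio was 5.22 with all libraries thinned to the smallest. Thinning took more counts from CPEB1-KO than from WT, so it was unlikely to lower the ratio and adds little. The ratio was 3.62 with the neuron marker covariate and 3.88 with the length trend removed, which argues against each of these 2 as the whole cause. The ratio ranged from 2.82 (without WT replicate 3) to 9.98 (without CPEB1-KO replicate 2) when 1 library was left out, and it was 1.97 when each pair of groups was fitted by itself. With the 3 libraries left out together it was 4.16, and with DESeq2 on all libraries 3.07. Genotype and the spread among libraries of a group stay open as untested, and the interaction test called 1 gene.

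For the 4 comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. Real and highest other counts were 4185 and 0 for WT-LPS against WT, 952 and 1 for CPEB1-KO-LPS against CPEB1-KO, 5 and 0 for CPEB1-KO against WT, and 1 and 1872 for CPEB1-KO-LPS against WT-LPS. The split with 1872 genes exchanges WT-LPS replicate 1 and CPEB1-KO-LPS replicate 3, as does the split with 2577 genes over both treatments, which points to a structure of the samples. Each library was compared at the genes called over both treatments without it. There WT-LPS replicate 1 was nearer to the libraries of its own label at 13 of 27 genes (48.1%). For CPEB1-KO-LPS replicate 3 this was 15 of 47 (31.9%), against 80% to 100% in the other 10 libraries. At Gm13304, chosen after its values were seen and called with these labels, WT-LPS replicate 1 was at 53.0 TPM and CPEB1-KO-LPS replicate 3 at 0.25 TPM, each on the side of its own label. Pnp2 had 20.38 counts in WT-LPS replicate 1 and 0 in CPEB1-KO-LPS replicate 3, and Rpph1 28 and 0, also on the side of their own labels. The values go both ways, so whether these 2 labels are right stays open. In these 4 comparisons 1, 1, 1 and 2 splits gave as many genes as the real one, itself included.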

How the results depend on the processing

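The tests with the neuron marker covariate, with 3 libraries left out together, with the length trend removed and with thinned libraries were chosen only after the result was seen, and the other settings were fixed before. Of the values of the genes that the text names, 7848 kept their direction and their side of the threshold over all settings, 296 lost their call, 203 gained one, 99 without a call changed sign, and 2 reversed. The reversed gene was Hbb-bs in CPEB1-KO-LPS against CPEB1-KO, which was at 0.04 with all libraries, -1.75 with 3 libraries left out together (WT replicate 1, WT-LPS replicate 1 and CPEB1-KO-LPS replicate 3) and -1.73 to 0.54 without 1 library, the lowest without CPEB1-KO-LPS replicate 3. The level of Cpeb1 in knockout against wild type was not called in any setting. Fewer genes pass a test against 1.5-fold by its construction: 1720 in WT-LPS against WT, 417 in CPEB1-KO-LPS against CPEB1-KO, 3 in CPEB1-KO against WT, 0 for the interaction and 6 over both treatments. DESeq2 called 1655 genes in CPEB1-KO-LPS against CPEB1-KO, 500 in CPEB1-KO against WT, 90 in CPEB1-KO-LPS against WT-LPS, 293 for the interaction and 108 over both treatments. It made more false calls on simulated data, whose spread was the one that edgeR estimated. In CPEB1-KO against WT, the 5 calls became 11 without a filter, 3 with the replicate block, 9 with log2(TPM + 1), 10 with the neuron covariate and 9 with thinned libraries. In CPEB1-KO-LPS against WT-LPS, the 1 call became 3 without a filter, 4 with log2(TPM + 1), 9 with log2(TPM + 0.1), 5 over all genes above 0 and 8 with the neuron covariate. For the interaction, the 1 call became 2 with log2(TPM + 1) and 0 with RLE, log2(TPM + 0.1), all genes above 0, the neuron covariate, the length trend removed or thinned libraries, beside 2365 genes at an unadjusted p under 0.05 with edgeR. Over both treatments, the 17 calls became 10 with the replicate block and 9 with thinned libraries. A fit of WT and WT-LPS alone called 2592 genes, with fewer residual degrees of freedom. With the 3 libraries left out together, 3769 genes were called in CPEB1-KO against WT, 2813 in CPEB1-KO-LPS against WT-LPS, 1367 for the interaction and 3065 over both treatments. These libraries were picked because they lay apart from their groups, which lowers the spread, so these counts overstate the evidence. Apart from these reasons the cause was not tested. The 62 list calls became 2 with an estimated correlation. The Pearson r of the LPS responses (0.68) was 0.809 over called genes, 0.453 without a filter and 0.548 without the 3 libraries, and that of the genotype differences (0.025) was 0.522 over the 5 called genes, too few to read, -0.0808 with the neuron covariate and 0.182 without the 3 libraries. Leaving out 1 library gave 2714 to 4724 genes in WT-LPS against WT, 355 to 1132 in CPEB1-KO-LPS against CPEB1-KO, 2 to 1292 in CPEB1-KO against WT, 1 to 11 in CPEB1-KO-LPS against WT-LPS, 0 to 441 for the interaction, 5 to 47 over both treatments, r of 0.580 to 0.704 for the LPS responses and r of -0.0958 to 0.130 for the genotype differences, and the report names the libraries behind changes over 1.5 times. Fits of 2 groups alone give no value for the interaction or over both treatments. On data simulated at 5.02 to 13.54 M counts with 3 libraries per group, edgeR called 28% of genes planted at 2-fold. Fewer genes were changed there than were called in WT-LPS against WT. In that comparison 2812 of the 4185 called genes changed at least 2-fold, so smaller changes were called too. The 28% therefore does not carry over to it.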

Other observations

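Of the tests in this part, the permutation tests of cell marker lists were planned, and their use on the homeostatic microglia list was chosen only after the result was seen.

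Mean log2(TPM + 1) of the homeostatic microglia list was 7.47 ± 0.123 (SD, n = 3) in WT and 6.60 ± 0.282 in CPEB1-KO, without overlap (exact permutation p = 0.1, the smallest that 3 against 3 can give). With LPS the genotypes overlapped, at 5.61 ± 0.724 in WT-LPS and 4.94 ± 0.943 in CPEB1-KO-LPS (exact permutation p = 0.5). Without LPS, neuron markers were higher in CPEB1-KO without overlap (6.89 ± 0.870 in WT and 8.19 ± 0.215 in CPEB1-KO), and erythroid markers lower (9.78 ± 0.265 and 9.18 ± 0.228), at the same p of 0.1. Over 11 lists of cell markers and 4 comparisons, 14 of 44 pairs of groups did not overlap, where chance gives 10%. C4b, a complement gene, was at 1.38 ± 0.40 in CPEB1-KO against WT without passing the threshold. Ddx3y, on the Y chromosome, was at 21.01 to 58.01 TPM and Xist, which silences an X chromosome in females, at 0.12 TPM or less in every library.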
